A study of Mus musculus with 4 samples.

How the data were processed

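Gene expression was measured in satellite cells of 2 Tg:Pax7-nGFP mice. Per the labels' protocols, 5 ng of RNA per sample was made into cDNA by the SMART-Seq2 method, tagmented and converted to circular libraries. SMART-Seq2 amplifies full-length cDNA and does not mark the strand, so reads of a gene and its antisense partner cannot be told apart. The submitters' processing notes name the GRCm38 build, HISAT2 2.1.0 and StringTie 1.3.6. The annotation release, the read length and the steps from coverage to counts are not given in the sources used here.

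The deposited tables hold estimated counts and TPM for 55487 gene identifiers. The authors' estimated counts are whole numbers. Among genes with 1 annotated transcript, over 500 counts and a TPM above 0, the count equalled transcript length times TPM times 1 constant per library within 1% for at least 99.96% of genes. The low counts pile up at 4, 8 and 12, so 1 fragment may be worth about 4 counts, and the totals of 230431665 to 355411827 cannot be read as depth in fragments. The authors' deposited TPM values are scaled to transcript length and library. Mitochondrially encoded genes took 3.98% to 4.47% of the counts, and the rRNA-like genes AY036118 and CT010467.1 took 8.95%, 6.53%, 5.00% and 5.06% in the control and Numb exon 6 libraries of mouse 1 and mouse 2. Coordinates and transcript models come from GENCODE vM21 on GRCm38, which holds 55094 of the identifiers.

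Groups and mice were taken from the labels, and the libraries of each mouse were treated as separate samples of 2 animals. The main test was fixed before the data were examined: edgeR 4.0.16 in R 4.3.3, quasi-likelihood with robust estimation, TMM factors, the default expression filter by group, no block, and Benjamini-Hochberg adjustment at 0.05. Log2 fold changes are Numb exon 6 minus control morpholino, with the SE derived from the quasi-likelihood statistic. CPM values are scaled by TMM. Log2 ratios within a mouse are differences of log2 CPM with a prior count of 2.

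The series design names no statistical model, so the main test has no block. The same-numbered samples come from the same animal, so the mouse pairs the samples. The SE of the main test therefore takes in the difference between the mice. After removal of group means, libraries of the same mouse deviated together, with a correlation across genes of 0.41 at a mean log2 CPM of 3 or more and of 0.06 over all tested genes. The leading principal component (49.8% of the variance) parted the mice and the next (30.2%) parted the morpholinos. The mice were compared, 1 animal against 1, with the mouse as the only term.

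The 31 gene lists covered Notch targets and machinery, partners of Numb, myogenic states, stress, metabolism, ribosomes and markers of 9 cell types, all fixed before the data were examined. Lists with 5 or more measured members were tested with camera in limma 3.58.1 on log2 CPM at a preset correlation of 0.01, and again with an estimated correlation and with fry. With 4 libraries and no block, the correlation is estimated from little information and, for the morpholinos, takes in the difference between the mice. A failure with it therefore does not settle a call. Symbols shared by more than 1 identifier were all kept. The genes named were 18 fixed genes, up to 5 per direction with the smallest p at a mean log2 CPM of at least 3 and the same sign in both mice (since none was called), the 4 members with the smallest p of each called list, and the 2 most abundant members of each marker list. Unnamed gene models were skipped. Genes named outside this rule are said to be chosen after their values were seen, or are the full set behind a count.

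The alternatives were the mouse block, other size factors, other filters, DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1) and log2(TPM + 0.1), removal of mitochondrial genes and of each library in turn. Added after the data were seen were counts divided by 4 and rounded, removal of the rRNA-like genes, removal of GC content and length trends, and a stricter filter with an estimated correlation. The tests were checked on counts simulated for the 27551 genes of the morpholino comparison with 200 genes changed. Of 100 genes changed 2-fold, edgeR called 29, DESeq2 78 and limma-voom 46, and of 100 changed 4-fold they called 98, 100 and 98. False calls numbered 13, 131 and 17 in the same order. The simulation held no difference between the mice, and its 200 changed genes ease the adjustment. Its shares need not hold for the real data, where the absence of calls does not exclude 4-fold changes. Splicing of exon 6 was not analysed here, since only values per gene were used.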

Results

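RNA from muscle stem (satellite) cells of Tg:Pax7-nGFP mice was sequenced after minced skeletal muscle had been treated with a vivo-morpholino, an antisense oligomer carried into cells without transfection, during the initial digestion step. One morpholino blocks inclusion of exon 6 of Numb, an endocytic adaptor known as an inhibitor of Notch signalling, and the other was a control morpholino. Each of 2 mice gave 1 library per morpholino, so each group held 2 libraries and 4 were compared in all. The estimated counts summed to 355411827 and 318663258 in the control and Numb exon 6 libraries of mouse 1, and to 306485954 and 230431665 in those of mouse 2. These counts were derived from coverage, so the totals cannot be read as numbers of sequenced fragments.

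The comparison of the morpholinos asked which transcripts follow the block of Numb exon 6 during satellite cell activation. Transcripts of the Numb gene (GRCm38 chromosome 12, 83794034 to 83921934) stood at 44.6 CPM in the control and 60.3 CPM in the Numb exon 6 library of mouse 1, and at 53.8 and 58.7 CPM in mouse 2. The log2 fold change was 0.27 ± 0.14 (SE, n = 2 per group), with an edgeR adjusted p of 0.999. Counts per gene do not separate transcripts with exon 6 from those without it, so they do not show whether its splicing was altered. Rbfox2, the splicing factor named in the title of the study, stood at 164 and 328 CPM in the controls of mouse 1 and mouse 2, and its log2 ratios within them were -0.41 and -0.38. Its log2 fold change was -0.39 ± 0.45 (SE), and -0.40 ± 0.08 (SE; edgeR adjusted p = 0.796) with the mouse as a block. Numbl, the paralogue of Numb, had a log2 fold change of -0.24 ± 0.20 (SE).

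None of the Notch pathway transcripts passed the test. Among direct targets of Notch, Hey1 had a log2 fold change of 0.41 ± 0.31, Heyl of 0.34 ± 0.21 and Hes1 of 0.16 ± 0.18 (SE, n = 2 per group). The receptors Notch1, Notch2 and Notch3 had log2 fold changes of -0.26 ± 0.16, -0.005 ± 0.134 and 0.02 ± 0.10 (SE), and Calcr, a target active in quiescent satellite cells, -0.07 ± 0.29. With the mouse as a block, Hey1, Heyl, Hes1 and Notch1 had 0.39 ± 0.09, 0.36 ± 0.10, 0.18 ± 0.14 and -0.25 ± 0.09 (SE). Their unadjusted edgeR p values were then 0.011, 0.017, 0.257 and 0.039, and the adjusted ones ran from 0.796 to 0.857. Of the 21 measured Notch targets, 9 were higher and 2 lower in both mice, with a median log2 fold change of 0.08. By edgeR 0 of the 21 passed the threshold over all genes and 0 when adjusted over the list alone, while 2 had an unadjusted p under 0.05 (Snai2 and Dtx4), and 6 with the mouse as a block, which called 0 as well. DESeq2 and limma-voom also called 0 of them over the list alone. As a set the targets did not pass either (limma camera, adjusted p = 0.290). The 38 receptors, ligands and processing factors of the pathway had a median of 0.02, and the 34 endocytic and polarity partners of Numb a median of 0.01.

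Among the myogenic regulators, Myod1 was the most abundant, at a mean of 1236 CPM with the control and 1322 CPM with the Numb exon 6 morpholino. Myf5, which marks commitment to the myogenic lineage, stood at 537 and 386 CPM with the control morpholino and at 900 and 623 CPM with the Numb exon 6 morpholino. Its log2 fold change of 0.72 ± 0.24 (SE, n = 2 per group) did not pass over all genes (edgeR adjusted p = 0.999, and 0.404 in DESeq2), while DESeq2 with the mouse as a block called it (adjusted p = 3.1e-06). The log2 fold change was 0.43 without the Numb exon 6 library of mouse 1 and 0.98 without the control library of mouse 1. With the mouse as a block, its edgeR p adjusted over the list alone was 0.0049 among 23 commitment genes and 0.0039 among 18 satellite cell markers. Pax7, the transcription factor that defines satellite cells, had a log2 fold change of 0.27 ± 0.18, Myod1 of 0.10 ± 0.13 and Myog, a differentiation factor, of 0.10 ± 0.26 (SE). The immediate early gene Fos had one of 0.44 ± 0.11, and the cell cycle genes Cdkn1a, Ccnd1 and Mki67 had -0.09 ± 0.26, 0.07 ± 0.19 and -0.29 ± 0.57 (SE).

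**Figure D1:**
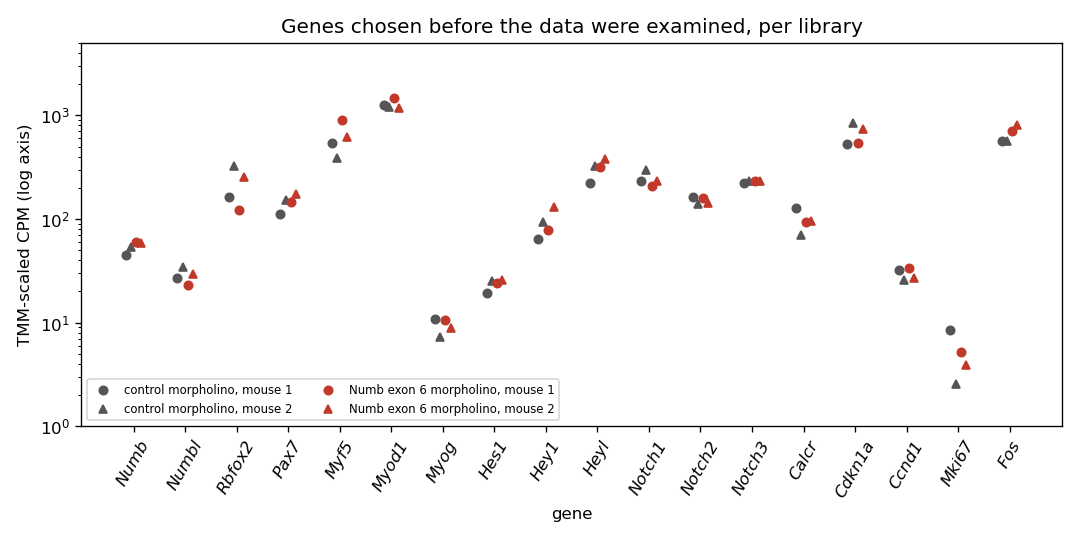
TMM-scaled CPM, on a log axis, of the 18 genes chosen before the data were examined, with 1 point per library (grey for the control and red for the Numb exon 6 morpholino, circles for mouse 1 and triangles for mouse 2). Myf5 is higher with the Numb exon 6 morpholino in both mice, and Rbfox2 is lower in both, from unequal levels in the controls.

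Over all 27551 tested genes, edgeR called 0 higher and 0 lower with the Numb exon 6 morpholino, while 1145 had an unadjusted p under 0.05, which is 4.16% of those tested. The smallest adjusted p was 0.172. With the mouse as a block edgeR also called 0, with 1677 (6.09%) at an unadjusted p under 0.05 and a smallest adjusted p of 0.257. DESeq2 called 39 genes higher and 26 lower, and 104 and 55 with the mouse as a block; limma-voom called 0, with 1140 at an unadjusted p under 0.05. Counts were also simulated from these libraries, with changed genes added and no difference between the mice. On them DESeq2 without the block made 131 false calls and edgeR 13. The changed genes ease the adjustment, so these numbers do not show how many real calls of DESeq2 without the block are false. DESeq2 with the block was not simulated, so these numbers do not bear on its calls. All 65 calls of DESeq2 without the block had an unadjusted p under 0.05 in edgeR, and 60 were also called with the block. Without a filter on low counts edgeR called 5 genes higher and 5 lower, and with a CPM of at least 5 in 2 libraries it called 1 higher.

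Genes were then ranked by p among those with a mean log2 CPM of at least 3 and the same direction in both mice; none passed in the main edgeR test. The 5 highest ranked of the genes with higher values were Fam107b, Clcn5, Bzw1, Zbtb4 and Creb5, whose log2 fold changes were 2.42 ± 0.19, 1.93 ± 0.16, 0.97 ± 0.11, 3.66 ± 0.43 and 0.67 ± 0.10 (SE, n = 2 per group). The edgeR adjusted p was 0.425 for Fam107b and Clcn5 and higher for the other three. Clcn5, a chloride-proton exchanger of endosomes, stood at 13.2 and 13.4 CPM in the controls and at 45.4 and 55.9 CPM in the Numb exon 6 libraries. In TPM, which is scaled to transcript length, Clcn5 stood at 7.73 and 8.74 in the controls and at 13.3 and 16.2 in the Numb exon 6 libraries, and its log2 fold change on log2(TPM + 1) was 0.77. On that scale those of Zbtb4 and Creb5 were 2.17 and 0.35. Of the genes with lower values they were Cbx3, Atp6v0c, Pprc1, Srp14 and Ncoa5, with -2.22 ± 0.18, -0.95 ± 0.11, -0.87 ± 0.11, -1.06 ± 0.14 and -1.12 ± 0.15 (SE). Cbx3, a heterochromatin protein, stood at 47.8 and 43.9 CPM in the controls and at 8.75 and 10.9 CPM in the Numb exon 6 libraries (edgeR adjusted p = 0.425). Without a filter on low counts edgeR called Fam107b, Clcn5, Bzw1, Cbx3 and Atp6v0c (adjusted p = 7.8e-04, 8.6e-04, 0.0306, 5.1e-04 and 0.0306) and not the other 5. Each of these 10 genes was called by DESeq2. Ntn1, which encodes the guidance cue netrin, lay under that expression limit and was chosen after its values were seen. It had the smallest p of all genes, with estimated counts of 221 and 208 in the controls and 3549 and 3125 in the Numb exon 6 libraries (log2 fold change 4.22 ± 0.23, SE; edgeR adjusted p = 0.172), and a log2 fold change of 2.04 on log2(TPM + 1). It was the gene called with a CPM of at least 5 in 2 libraries (adjusted p = 0.036), and it was called without a filter (4.9e-05).

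Of the 8540 genes at a mean log2 CPM of 3 or more, 12 differed over 2-fold in the same direction in both mice, 5 of them higher and 7 lower, and 10 differed over 2-fold in opposite directions. Across these genes the log2 ratios of the mice had a Pearson correlation of 0.18 and a Spearman correlation of 0.27; genes are not independent replicates. Akt2, chosen after its values were seen, was among the 10, with log2 ratios of 1.32 in mouse 1 and -1.31 in mouse 2. Zbed6 and Zc3h11a, which were lower in both mice, are overlapping gene models whose counts cannot be separated with certainty, and their pooled log2 ratios were -0.07 in mouse 1 and 0.03 in mouse 2.

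**Figure D2:**
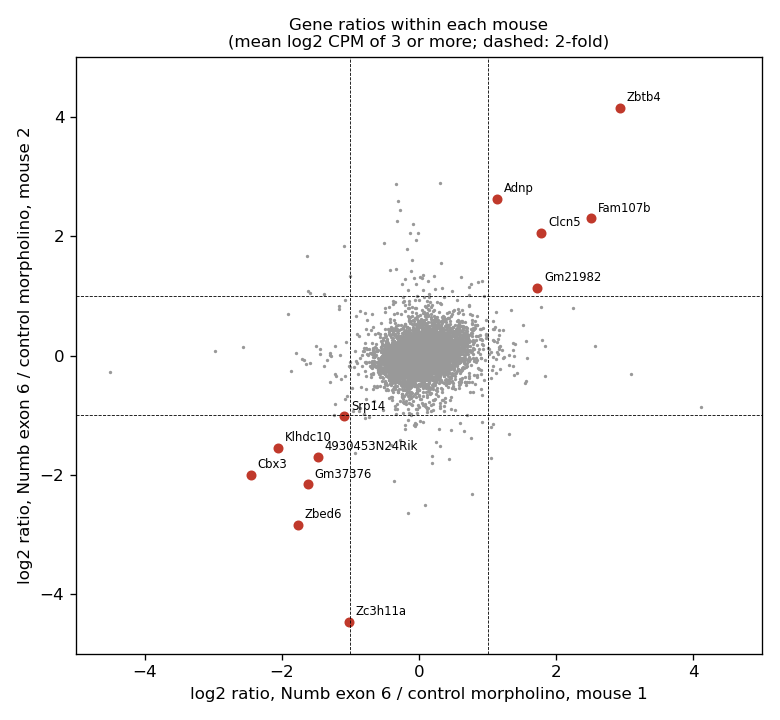
Log2 ratio of the Numb exon 6 over the control morpholino for each gene with a mean log2 CPM of 3 or more, mouse 1 on the horizontal and mouse 2 on the vertical axis; dashed lines mark 2-fold. The 12 named red points are over 2-fold in the same direction in both mice, and 3 of the 8540 genes lie outside the axes.

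Genes of ribosome production were slightly lower with the Numb exon 6 morpholino. Of 40 ribosome biogenesis genes, 31 were lower in both mice and 0 higher, with a median log2 fold change of -0.23 (limma camera, adjusted p = 0.0011). With an estimated correlation its adjusted p was 0.907. That test gave 0 of the 31 lists an unadjusted p under 0.05. It put the correlation between the biogenesis genes at 0.70, against the preset 0.01. The estimate comes from 4 libraries without the block, so neither camera value settles the call. The nucleolar genes Nhp2, Ncl, Nolc1 and Fbl had log2 fold changes of -0.33 ± 0.12, -0.36 ± 0.15, -0.34 ± 0.14 and -0.24 ± 0.10 (SE, n = 2 per group), none past the edgeR threshold. With the mouse as a block the SEs were 0.09, 0.12, 0.08 and 0.08, and none passed either. Of the 40 genes, 1 had an unadjusted edgeR p under 0.05, and 17 with the block, against 6.09% of all genes. Neither fit called any over the list alone, and the genes of a list are not independent. Of 77 cytosolic ribosomal protein genes, 57 were lower and 9 higher in both mice, with a median of -0.12 (camera adjusted p = 0.0165, and adjusted p = 0.907 with an estimated correlation). Rpl38, Rpl37, Rpl7a and Rps29 had log2 fold changes of -0.37 ± 0.11, -0.29 ± 0.10, -0.31 ± 0.11 and -0.29 ± 0.11 (SE). Of the 77, 4 had an unadjusted edgeR p under 0.05, and 12 with the mouse as a block. Without the control library of mouse 1 the adjusted p of the biogenesis list was 0.705, and without the Numb exon 6 library of mouse 2 it was 0.222. The call of the ribosomal proteins was lost without any 1 of the 4 libraries, at adjusted p values from 0.0538 to 0.345, and once trends with GC content and length were removed (0.129).

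Leukocyte markers were higher with the Numb exon 6 morpholino, from very low levels. Of 20 measured, 15 were higher and 2 lower in both mice, with a median log2 fold change of 1.32 (limma camera, adjusted p = 8.4e-04, and adjusted p = 0.907 with an estimated correlation). Lyz2, the lysozyme of macrophages and neutrophils, stood at 4.32 and 4.21 CPM in the controls and at 8.24 and 14.2 CPM in the Numb exon 6 libraries. Fcer1g, Tyrobp and Itgam had log2 fold changes of 2.13 ± 0.47, 2.33 ± 0.72 and 1.59 ± 0.57 (SE, n = 2 per group), at fewer than 1 CPM per group. The neutrophil genes S100a8 and S100a9, chosen after their values were seen, were high in the Numb exon 6 library of mouse 2 alone (11.5 and 9.38 CPM, against at most 1.08 in the other libraries). The macrophage gene Cd68 had a log2 fold change of 0.02 ± 0.18 (SE). The 2 members lower in both mice, against the 15 higher, were Csf1r (-0.46 ± 0.31) and C1qa (-0.44 ± 0.89, SE). Over the list alone edgeR called 0 members, with 5 at an unadjusted p under 0.05 (0 and 8 with the mouse as a block), limma-voom 0, and DESeq2 3 (Tyrobp, Fcer1g and Lyz2). Without the control library of mouse 2 the list's adjusted p was 0.271.

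Markers of the remaining cell types did not pass as lists in the main test. Fibro-adipogenic progenitor markers were called higher with a CPM of at least 5 in 2 libraries (adjusted p = 0.0247), on log2(TPM + 1) (0.0073) and without the control library of mouse 1 (0.0387). Endothelial markers were called higher on log2(TPM + 1) (0.0055) and without the Numb exon 6 library of mouse 2 (2.6e-05), as were glial markers without that library (0.0044). For each of these lists the main test gave adjusted p = 0.907 with an estimated correlation. The median log2 fold changes were -0.07 for mature myofibres, 0.17 for fibro-adipogenic progenitors, 0.27 for endothelium, 0.19 for smooth muscle and pericytes, 0.25 for glia, 0.21 for tenocytes, 0.34 for erythroid cells and 0.10 for satellite cells. The endothelial and glial medians were 0.69 and 0.75 within mouse 1 and -0.05 and -0.21 within mouse 2. Of the most abundant members, the log2 fold changes were Actn3 0.11 ± 0.11 and Atp2a1 0.21 ± 0.14 of myofibres, Gsn -0.07 ± 0.10 and Col3a1 0.12 ± 0.20 of progenitors, Tek 0.14 ± 0.13 and Aqp1 0.28 ± 0.33 of endothelium (SE). Those of the other types were Des -0.16 ± 0.10 of smooth muscle and pericytes, Mal 0.11 ± 0.20 of glia, Thbs4 0.23 ± 0.13 and Fmod 0.31 ± 0.20 of tenocytes, Hba-a1 0.33 ± 0.55 and Hbb-bs 0.34 ± 0.51 of erythroid cells, and Sdc4 0.10 ± 0.09 and Vcam1 0.07 ± 0.23 of satellite cells. Pmp22, the myelin gene of the glial list, had a log2 fold change of 0.97 ± 0.23 (SE); its p adjusted over the list alone was 0.119 in edgeR and 0.0178 in edgeR with the mouse as a block. DESeq2 called it over the list alone and over all genes (adjusted p = 0.0293, and 5.1e-07 with the mouse as a block).

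The other lists did not pass in the main test either. Extracellular matrix genes were called higher on log2(TPM + 1) (adjusted p = 0.0138) and without the control library of mouse 1 (0.0387), and immediate early and interferon response genes without the control library of mouse 2 (0.0296 each). For each of them the main test gave adjusted p = 0.907 with an estimated correlation. Medians were 0.08 for satellite cell quiescence, 0.10 for immediate early genes, 0.06 for myogenic commitment, -0.03 for myogenic differentiation, 0.05 for the cell cycle, -0.04 for heat shock and dissociation stress, and 0.08 for p53 targets. They were 0.06 for the interferon response, 0.14 for cytokines, 0.04 for mitochondrially encoded transcripts, -0.05 for nuclear oxidative phosphorylation, -0.03 for glycolysis, 0.003 for the unfolded protein response and 0.05 for the extracellular matrix. Targets of TGF beta and BMP had a median of 0.13, those of Wnt, Hedgehog and FGF -0.07, and splicing factors -0.03. The adjusted p of the 28 lists that did not pass ran from 0.0796 for endothelial markers to 0.945. Adjusted over the list alone, edgeR called 0 members in the 31 lists, with 42 of 927 entries at an unadjusted p under 0.05, limma-voom 0 with 45, and DESeq2 5 with 54. With the mouse as a block edgeR called 5 entries over the list alone, with 138 of the 927 at an unadjusted p under 0.05. The 5 entries were Myf5, counted in both the commitment and the satellite cell marker lists, Dnaja4, Hspb1 and Pmp22. The chaperones Dnaja4 and Hspb1, chosen after their values were seen, with log2 fold changes of 0.60 ± 0.15 and 0.35 ± 0.13 (SE), had edgeR p values adjusted over the list alone of 0.0484 and 0.0491 with the mouse as a block. Fry, run without the block, called no list for a shift in 1 direction (1 list at an unadjusted p under 0.05). Its test for change in either direction called glycolysis (adjusted p = 0.0379). Like the main test, fry takes in the difference between the mice, so a failure in it does not settle a call.

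**Figure D3:**
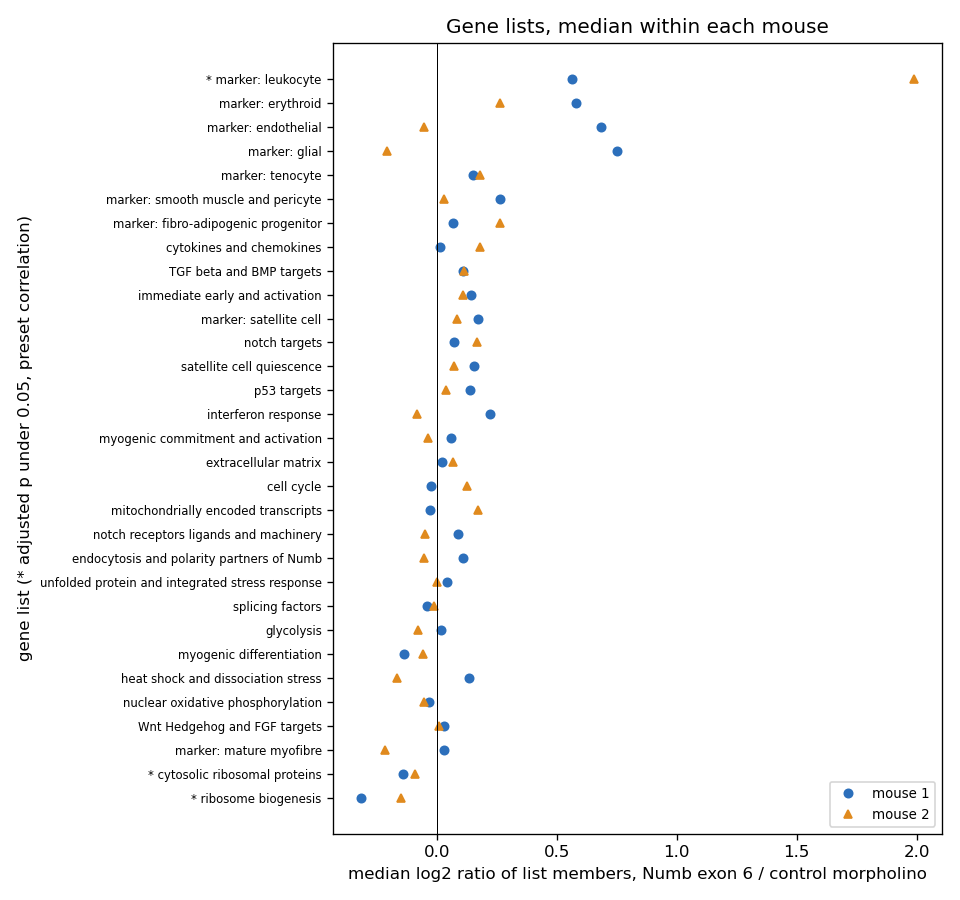
Median log2 ratio of the Numb exon 6 over the control morpholino for the measured members of each of the 31 gene lists, within mouse 1 (circles) and mouse 2 (triangles); asterisks mark lists with a camera adjusted p under 0.05 at the preset correlation. Leukocyte markers lie at 0.56 and 1.99 and ribosome biogenesis genes at -0.32 and -0.15 in mouse 1 and mouse 2.

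The 2 mice were also compared, 1 animal against 1. The libraries of each are its 2 morpholino treatments, so the SE and p values here measure the spread between libraries of an animal and not between animals. Inflammatory and immediate early transcripts were higher in mouse 2. Of 39 immediate early genes, 14 were higher when adjusted over the list alone, and the list median was 0.36 (limma camera, adjusted p = 1.7e-05, and adjusted p = 0.805 with an estimated correlation). Cxcl1, Ccl2 and Lif, secreted factors of inflammation and chosen after their values were seen, had log2 fold changes of 1.01 ± 0.08, 1.24 ± 0.12 and 1.297 ± 0.117 (SE, n = 2 libraries per mouse). None of them passed over all genes (edgeR adjusted p = 0.075, 0.128 and 0.113), and 7 of 29 cytokine genes were higher over the list alone. Globin transcripts were higher too, with 4 of 9 erythroid markers called over the list alone and a median of 1.16. Of 33 genes of the unfolded protein response, 8 were lower over the list alone, with a median of -0.23.

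Over all genes, edgeR called 3 higher in mouse 2 (Zscan26, Osgin1 and Gm47308) and 4 lower (Zfp180, Pcdhb21, Gm27300 and Gm3226), with 2290 at an unadjusted p under 0.05. Osgin1, an oxidative stress gene, had a log2 fold change of 1.56 ± 0.10 (SE; edgeR adjusted p = 0.0394). Pcdhb21 had estimated counts of 2338 and 1874 in mouse 1 and of 0 and 0 in mouse 2. With the morpholino as a further term the numbers were 0 and 1, and DESeq2 called 280 higher and 215 lower. By camera at the preset correlation 9 lists were called, and with an estimated correlation 0, none of them at an unadjusted p under 0.05. Beside the immediate early list, those of the interferon response, cytokines and erythroid markers were higher in mouse 2 (medians 0.28, 0.21 and 1.16). The unfolded protein response, ribosome biogenesis, extracellular matrix, fibro-adipogenic progenitor and endothelial lists were lower (medians -0.23, -0.22, -0.21, -0.23 and -0.39). Their adjusted p with an estimated correlation was 0.805 or 0.916.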

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

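The fits on counts divided by 4, without the rRNA-like genes, with GC content and length trends removed, and with the stricter filter and an estimated correlation were chosen after the results were seen. The edgeR counts of 0 genes higher and 0 lower kept those values with the replicate block, both other size factors, limma-voom, the 3 fits on TPM, and without mitochondrial or rRNA-like genes, and with counts divided by 4. They became 5 and 5 without a filter (Fam107b, Clcn5, Bzw1, Ntn1, Cbx3 and Atp6v0c among them), 1 and 0 with a CPM of at least 5 in 2 libraries, 39 and 26 with DESeq2, 104 and 55 with DESeq2 and the block, and 3 and 1 with counts divided by 4 and the block. Leaving out 1 library gave 0 to 1 higher and 0 lower; the single library of a group is then assumed to vary like the others. The log2 fold change of Numb ranged from 0.14 to 0.40 and did not pass under any alternative run. Gene lists called higher and lower numbered 1 and 2. They became 0 and 0 with an estimated correlation, with fry, and with the stricter filter and an estimated correlation. They were 4 and 2 on log2(TPM + 1), and 1 and 1 with trends removed. Leaving out 1 library gave 1 to 3 higher and 0 to 1 lower. The adjusted p was 0.907 for each called list with an estimated correlation and 0.817 with fry, and 0.887 for ribosome biogenesis and 0.895 for ribosomal proteins with the stricter filter and an estimated correlation. Leaving out 1 library gave 5.1e-06 to 0.705 for ribosome biogenesis, 0.0538 to 0.345 for ribosomal proteins and 1.9e-06 to 0.271 for leukocyte markers. Under the stricter filter too few leukocyte markers were left to test. With trends removed the ribosomal protein list had an adjusted p of 0.129, as its median moved from -0.12 ± 0.01 to -0.09 ± 0.02 (SE over genes), closer to 0. Between the mice, 3 higher and 4 lower became 0 and 1 with the morpholino as a term, 80 and 39 without a filter, 36 and 7 with the stricter filter and 280 and 215 with DESeq2. Among fixed genes, the log2 fold change of Notch2 was 0.0544, 0.0562 and 0.0544 and that of Calcr 0.0214, 0.0229 and 0.0214 on log2(TPM + 1), log2(TPM + 0.1) and log2(TPM + 1) unfiltered, and that of Notch3 was -0.0231 with upper-quartile factors. Leaving out 1 library turned the sign for Rbfox2 (-0.999 to 0.18), Myod1 (-0.0708 to 0.24), Myog (-0.17 to 0.42), Hes1 (-0.0238 to 0.37), Hey1 (-0.0096 to 0.72), Notch2 (-0.12 to 0.11), Notch3 (-0.0219 to 0.0542), Calcr (-0.44 to 0.43), Cdkn1a (-0.39 to 0.27), Ccnd1 (-0.10 to 0.25) and Mki67 (-0.92 to 0.82). It moved by over 1.5 times, with no turn of sign, Numbl (-0.43 to -0.066), Pax7 (0.071 to 0.49), Myf5 (0.43 to 0.98), Heyl (0.087 to 0.63), Notch1 (-0.42 to -0.081), Ncl (-0.54 to -0.17) and Nolc1 (-0.49 to -0.19). These fits break a pair, so a level that differs between the mice, as for Rbfox2, moves them. At the main filter and factors the block changed no edgeR call over all genes and no camera call. With it DESeq2 called Myf5 (adjusted p = 3.1e-06), and edgeR on counts divided by 4 called Fam107b and Clcn5 (0.0467 each) and Ntn1 (0.0409). Other lists were called under single alternatives, as named in the report. Apart from the trends, the fewer samples and the genes tested, the cause was not tested. At low counts, as for the 7 of 20 leukocyte markers with fewer than 100 counts in both control libraries, depth limits what can be told.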

Other observations

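The tests on overlapping gene models, on transcript length, on the control library of mouse 1 and on trends with GC content and length were chosen after the result was seen, as was the interval around the share of mast cell genes. The other tests were not, though some mast cell genes had been seen before the mast cell test, which left those genes out.

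The mast cell proteases Tpsb2, Cpa3, Cma1 and Mcpt4, chosen after their values were seen, were detected almost solely in the Numb exon 6 libraries. Tpsb2 had estimated counts of 250 and 185 in the Numb exon 6 libraries of mouse 1 and mouse 2, and of 5 and 0 in the controls. Cpa3 had 151 and 95 against 3 and 0, Cma1 200 and 110 against 0 and 4, and Mcpt4 146 and 52 against 4 and 0. None passed in edgeR (adjusted p = 0.999 for each), while DESeq2 called all 4 (adjusted p = 1.7e-07, 2.8e-04, 8.5e-05 and 0.0173 in the order given) and did so with the mouse as a block as well. Each control value is at most 5 counts. Kit, another mast cell gene chosen after its values were seen, had 14 and 53 in the controls of mouse 1 and mouse 2 and 23 and 39 in the Numb exon 6 libraries. Another protease, Tpsab1, was 1 of 18 mast cell genes listed before their values were looked at, and is named here after they were. It had 11 and 29 in the control and Numb exon 6 libraries of mouse 1 and 0 in both of mouse 2. Mrgprb1, also of these 18 and named after its values were seen, had 6 and 143 in those of mouse 1. In those of mouse 2 it had 12 and 35 (edgeR adjusted p = 0.999). Of the 13 detected genes among the 18, 3 were higher and 2 lower in both mice. The immediate early genes Egr2 and Nr4a1, chosen after their values were seen, had log2 fold changes of 0.47 ± 0.15 and 0.51 ± 0.19 (SE, n = 2 per group) and were higher in both mice (edgeR adjusted p = 0.999 for both).

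Leukocyte markers were higher with the Numb exon 6 morpholino. Noise of genes near the detection limit is argued against by the list median, which lay at percentile 100 among 10000 expression-matched random lists. RNA of mast cells stays open: of 13 detected mast cell genes not looked at before, 3 were higher in both mice (23.1%, exact binomial 95% interval 5.04% to 53.8%). That share meets the limit of at most 1 of 3 set beforehand for excluding them, but its interval, chosen after the share was seen, reaches above the limit, and 10 of the 13 had 50 or more counts in a control library, which would hide a small share. The control library of mouse 2 stood lowest. The list medians, relative to the mean of each gene, were 0.16, 0.65, -0.73 and 0.40 for the control and Numb exon 6 libraries of mouse 1 and mouse 2. Among the fits that left out 1 library, the list lost its call only without that control library. That fit breaks a pair, so it does not settle whether that library alone sets the result. The median log2 ratio within mouse 1, which does not use it, was 0.56. A chance difference in the few leukocytes carried through isolation and an effect of the Numb exon 6 morpholino on leukocytes in the digest were not tested, and the adjusted p with an estimated correlation was 0.907.

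Ribosome biogenesis genes were lower with the Numb exon 6 morpholino, with list medians of -0.32 within mouse 1 and -0.15 within mouse 2. Of the 40 genes, 31 were lower and 0 higher in both mice. At the preset correlation the camera adjusted p was 3.8e-04 with the mouse as a block and 0.0011 without it. With an estimated correlation and no block the camera adjusted p was 0.907. An estimated correlation with the block was not run. A trend with GC content and transcript length is argued against as the whole cause, since the list kept an adjusted p of 3.2e-04 at the preset correlation after trends were removed. The control library of mouse 1 alone stays open: without it the adjusted p was 0.705, and the median of -0.148 within mouse 2 compares 1 library with 1 and has an SE of 0.117 once widened by the estimated correlation of 0.70 between the genes. That correlation was estimated without the block, so it takes in the difference between the mice, which cancels within a mouse. Before widening the SE was 0.022, with the genes taken as independent. The fit without the control library of mouse 1 breaks a pair and takes in that difference too, so neither value settles the question. The control library of mouse 1 stood highest, with medians of 0.26, -0.05, -0.05 and -0.17 for the control and Numb exon 6 libraries of mouse 1 and mouse 2. The rRNA-like genes took 8.95%, 6.53%, 5.00% and 5.06% of their counts in that order. Whether library or RNA quality sets that control library apart was not tested. A lower ribosome production with the Numb exon 6 morpholino may be followed up as a hypothesis, and it rests on 2 mice.

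The 12 genes over 2-fold apart in the same direction in both mice included Clcn5, whose mean transcript length was 3161 and 2957 bases in the controls and 6677 and 6772 bases in the Numb exon 6 libraries. Reads divided among overlapping gene models may account for 4 of the 12 (Zbed6, Zc3h11a, Gm21982 and Adnp), of which 0 stayed over 2-fold after such models were pooled; pooling tests little in the other 8, of which 1 (Gm37376) overlaps another model, on the opposite strand, and fell under 2-fold when pooled with it. Noise in single libraries stays open for the set, with a ratio of 1.2 between genes over 2-fold in the same and in opposite directions. A shift between transcripts of one gene also stays open. It was examined in 8 of the 12 genes, Adnp among them. These had more than 1 annotated transcript and at least 200 counts in every library. Their median change in mean transcript length was 0.40 on the log2 scale (percentile 100 among 10000 matched random sets). In 7 of the 8 the length changed in the same direction in both mice. Genes picked for a large count change tend to change in length, however, and the opposite-way genes had 0.13 (exact one-sided permutation p = 0.0758, on sizes alone). An effect of the Numb exon 6 morpholino on these genes stays open, untested, and sequence matches of the morpholino outside Numb were not analysed here.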
